A study of Caenorhabditis elegans with 4 samples.

How the data were processed

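RNA was measured in whole-body samples of Caenorhabditis elegans strain CF1041, which carries the daf-2(e1370) mutation in the insulin/IGF-1 receptor gene. Per the labels, animals were fed bacteria that make double-stranded RNA from the egg stage on, with 10 mM IPTG to induce it, and were moved to plates with 10 µM FUdR, which stops progeny from hatching. They were sampled on day 1 of adulthood. The groups were 2 libraries on control RNAi and 2 on hsf-1 RNAi. Per the labels' protocols the libraries were unstranded TruSeq mRNA libraries sequenced as read pairs, so reads from a gene and from an antisense partner cannot be told apart.

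The deposited files hold 1 expected count per gene and library, made by the authors, with no normalization. Expected counts are estimates that need not be whole, because reads that match several genes are shared out between them. A value within 0.004 of a whole number was taken as whole. RSEM 1.3.1 and STAR 2.7.0e are named in the submitters' processing notes, which also name HISAT2 2.0.5, StringTie 1.3.3, limma 3.24.15 and R 3.1.3 without giving their roles. The same notes name the builds WBcel235 and ce11. The annotation release and any read filter are not stated. Each file has 46904 rows with the same gene identifiers. Of these, 44017 have a symbol or sequence name in the reference table and 2887 do not. Coordinates come from the Ensembl 115 annotation of WBcel235, which holds 46817 of the identifiers.

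Library totals were 24480823 and 25845237 expected counts on control RNAi and 21852917 and 25135947 on hsf-1 RNAi. A single count is worth 0.0391 to 0.043 CPM, the usual per-library scaling of counts, here with TMM-scaled totals, and a floor of 3 counts is worth 0.117 to 0.129 CPM. Floors and counting intervals cover counting error only. A fold against a group with 0 counts in both libraries was computed against the mean floor of 3 counts per library and is a lower bound. For 1 to 3 counts over a group the ratio is given with its exact 95% binomial interval. Libraries of the same group differed by more than counting error. A chi-square comparison reached an unadjusted p under 0.05 for 59.1% of genes in the control pair and 45.4% in the hsf-1 RNAi pair.

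Expected counts were rounded to whole numbers and fitted with edgeR 4.0.16 in R 4.3.3, with filterByExpr at a minimum count of 10, TMM scaling, and the quasi-likelihood F-test for hsf-1 RNAi against control RNAi. P-values are 2-sided and were adjusted by the Benjamini-Hochberg method over the 14639 genes tested, with a threshold of 0.05. The standard error (SE) of a log2 fold change is its size divided by the square root of its F statistic. CPM values use the TMM-scaled library totals and are given as mean ± SD over 2 libraries. The p-values measure only the spread between samples, and no label says that the libraries come from separate cultures. The biological coefficient of variation was 22.4%.

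For naming, hsf-1, zip-10 and daf-2 were taken whatever their result. Among genes past the threshold with a mean of at least 5 CPM and both libraries of one group above both of the other, the 12 largest rises and 12 largest falls were taken. In each gene list, up to 4 members past the threshold with the smallest adjusted p were taken, or the 2 most abundant members where none passed. Other genes that the text names were chosen after their values were seen. These are hsp-16.2, hsp-70, hsp-1, hsp-90, sysm-1, zip-1, zip-6, skr-3, Y38C1AB.5, cpr-4, lys-3, spp-3, spp-27, ilys-5, clec-186, ifc-1, ifc-2, ifd-1, ifd-2 and ifp-1, and the other genes named only in the closing section.

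The 37 gene lists covered small heat shock proteins, cytosolic chaperones, the CCT chaperonin with prefoldin, endoplasmic reticulum and mitochondrial chaperones, the proteasome, autophagy, DAF-16 targets, genes low in daf-2 mutants, insulin signalling, insulin-like peptides and zip-family bZIP factors. They also covered PMK-1 and ATF-7 dependent genes, PMK-1 pathway components, ZIP-2 and surveillance genes, the intracellular pathogen response, lysozymes with saposin-like genes, epidermal antimicrobial peptides, C-type lectins, cytochrome P450 genes, UDP-glucuronosyltransferases, glutathione S-transferases, SKN-1 and antioxidant genes, and fatty acid metabolism. The others were vitellogenins, collagens, ribosomal proteins, histones, and markers of germline, sperm, oocyte, zygotic embryo, intestine, muscle, pharynx, neurons and hypodermis. The lists were written from memory of the field. 10 of their names matched no identifier and were left out. Lists were tested against the other genes with camera of limma 3.58.1, with a preset correlation of 0.01, on log2 CPM with a prior count of 2, and Benjamini-Hochberg adjustment over the lists. Member counts are given over all genes tested and adjusted over the list alone.

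The samples, the test, the naming rule, the lists and all but 1 alternative were fixed before the data were examined. The alternatives were RLE size factors, library totals only, no filter on low counts, a filter of at least 5 CPM, DESeq2 1.42.0, limma-voom, each library left out in turn, the replicate number as a block, adjusted p thresholds of 0.01 and 0.1, a test against a 1.5-fold change, camera with an estimated correlation, and fry. A fit without the vitellogenin rows was added after the data were seen. Where leaving out a library leaves 1 in its group, that library is assumed to vary like the others.

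The fit was tested on simulated counts drawn with the means and library sizes of these libraries, with 200 of 14295 to 14325 tested genes changed, in 5 runs. For hsf-1 RNAi against control RNAi it recovered 42.8% of the 2-fold and 84.6% of the 4-fold changes, and 3.97% of its calls were false. The 200 changed genes were drawn from outside the gene lists and above a minimum mean count. Spread followed the trend with expression, with none particular to a gene. Simulated libraries were independent, whereas real libraries of the same number deviated together. These rates therefore need not hold for the real data. A list shifted by 2-fold was called in 5 of 5 runs with the preset correlation and in 0 of 5 with an estimated correlation, so the latter setting had little power in this design.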

Results

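Gene expression was measured by RNA sequencing in day 1 adult daf-2(e1370) animals, whose insulin/IGF-1 receptor has reduced function. The series concerns immune ageing and the bZIP factor ZIP-10, and the comparison asks which transcripts change when hsf-1, the gene of the heat shock transcription factor, is knocked down in this background. There were 2 libraries on control RNAi, with totals of 24480823 and 25845237 expected counts, and 2 on hsf-1 RNAi, with totals of 21852917 and 25135947. Fold changes are hsf-1 RNAi over control RNAi, coordinates are from WBcel235, and the named genes are protein-coding. P-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another tool is named.

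The targeted gene was lower in both hsf-1 RNAi libraries. hsf-1 (WBGene00002004, chromosome I, 11953507 to 11963085) was at 70.4 and 84.9 CPM in the control libraries and at 42.5 and 38.6 CPM in the hsf-1 RNAi libraries. Its means were 77.7 ± 10.3 CPM on control RNAi and 40.6 ± 2.72 CPM on hsf-1 RNAi (SD, n = 2). The log2 fold change was -0.94 (SE 0.14, 95% confidence interval -1.28 to -0.59, edgeR adjusted p 0.0383), which leaves 52.2% of the control level. Reads from the double-stranded RNA itself are not separable from the transcript, so the level checks the labels only in part. The fall lost significance in edgeR without control replicate 1 (-1.07, adjusted p 0.0533), without control replicate 2 (-0.79, adjusted p 0.0943) and without hsf-1 RNAi replicate 2 (-0.86, adjusted p 0.0532).

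The heat shock protein genes F44E5.4, F44E5.5 and hsp-16.1 were lower and 12 of 19 genes of the intracellular pathogen response were higher, alongside calls in both directions among antimicrobial genes and intestine markers. Of 14639 genes tested, 177 were higher and 64 lower on hsf-1 RNAi, 241 in all, so that 73.4% of the changes were rises. At least 2-fold changes were found for 222 genes, of which 169 were higher and 53 lower. The median change was 5.73-fold among the higher and 2.97-fold among the lower genes. In all 241 genes both libraries of one group lay above both of the other, as a call with 2 libraries per group nearly requires. The same was so for 39.1% of tested genes and is so for 33.3% by chance. A total of 22 changed genes had an expected count more than 0.004 away from a whole number, and 37 overlapped exons of another counted gene. DESeq2 called 586 genes, 371 higher and 215 lower, among them all 241. The count depended on single libraries. It was 96 without control replicate 1, 138 without control replicate 2 and 454 without hsf-1 RNAi replicate 2.

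**Figure D1:**
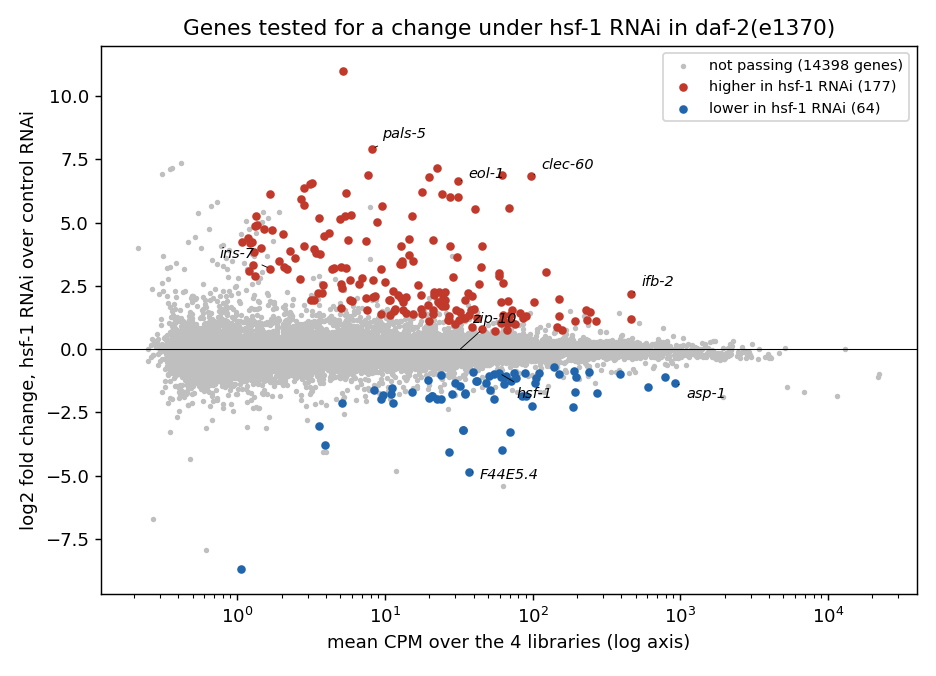
Log2 fold change on hsf-1 RNAi over control RNAi (vertical axis) against mean CPM over the 4 libraries (horizontal log axis), 1 point per tested gene. The 177 higher genes (red) had a median change of 5.73-fold and the 64 lower genes (blue) of 2.97-fold, and fitted changes of genes near 0 counts depend on the prior count.

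Among lower genes with a mean of at least 5 CPM, the 3 largest falls were those of the inducible chaperone genes F44E5.4, hsp-16.1 and F44E5.5. The heat shock 70 family genes F44E5.4 (WBGene00009691, chromosome II, 11757107 to 11759311) and F44E5.5 (WBGene00009692, chromosome II, 11759662 to 11761861) fell from 71.8 ± 17.8 to 2.48 ± 1.69 CPM and from 116.5 ± 6.26 to 7.26 ± 4.55 CPM (SD, n = 2). Their log2 fold changes were -4.84 (SE 0.47) and -4.0 (SE 0.41), with edgeR adjusted p of 0.0111 and 0.012. The small heat shock protein gene hsp-16.1 (WBGene00002017, chromosome V, 9090077 to 9090604) fell by 4.07 on the log2 scale (SE 0.64, edgeR adjusted p 0.0418). These genes share reads with near-identical copies, so their separate values are uncertain. The fall of hsp-16.1 lost significance in edgeR without control replicate 1 (adjusted p 0.0724) and without control replicate 2 (adjusted p 0.102). hsp-16.2 and hsp-70 had log2 fold changes of -4.08 (SE 0.97) and -2.35 (SE 0.67) but did not pass in edgeR (adjusted p 0.144 and 0.241). Over the alternatives their changes ran from -7.29 to -3.13 and from -3.73 to -1.67. hsp-16.2 passed in 3 of 11 alternatives and hsp-70 in 3 of 12. The constitutive chaperone genes hsp-1 (-0.16, SE 0.21) and hsp-90 (-0.33, SE 0.18) changed by less than the test could call, and hsp-1 was at 0.11 without control replicate 2. Below 5 CPM, 1 of 2 gene copies named Y38C1AB.5 (WBGene00021403) had 68.5 and 35 expected counts in the control libraries and 0 in both hsf-1 RNAi libraries, at least 17.3-fold lower. The other copy had the same control counts and 132 and 75 on hsf-1 RNAi, so the values of the copies are uncertain. Mean levels were 2.13 CPM for each copy on control RNAi, and 0 and 4.30 CPM on hsf-1 RNAi. The pair therefore did not fall, and the 17.3-fold value reflects how reads were shared out between the copies. The copy with 0 counts is still counted among the 64 lower genes. The call was lost in edgeR without control replicate 1 (adjusted p 0.109) and without control replicate 2 (adjusted p 0.0563).

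Across the small heat shock protein list, 1 of 15 tested members was lower, and adjusted over the list alone 2 were higher and 7 lower. The median log2 fold change was -0.21, between -0.61 and -0.41 with each library left out in turn. The mean was -1.65, and changes ran from -6.72 to 0.76, with 9 members negative and 6 positive. Camera did not call the list (adjusted p 0.0858), but did without hsf-1 RNAi replicate 1 (adjusted p 0.0201) and hsf-1 RNAi replicate 2 (adjusted p 0.000628). Lower members numbered 5 without hsf-1 RNAi replicate 1 and also without hsf-1 RNAi replicate 2, and 0 without control replicate 2. Among 21 cytosolic chaperones and co-chaperones, the 2 lower members were F44E5.4 and F44E5.5, 3 were lower adjusted over the list alone, and the median was -0.19. The list stood below other genes in camera (adjusted p 0.00152), but not without control replicate 2 (adjusted p 0.25) or with an estimated correlation (adjusted p = 0.707). All 14 CCT chaperonin and prefoldin genes had negative changes, between -0.39 and -0.018, and camera called the list down (adjusted p 0.0111, and adjusted p = 0.707 with an estimated correlation). It did not pass without control replicate 2 (median -0.12, adjusted p 0.21) or hsf-1 RNAi replicate 1 (adjusted p 0.14).

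The intracellular pathogen response had the largest median change of the 37 lists. All 19 tested members had positive changes, 12 passed over all genes tested, and 18 passed adjusted over the list alone, all but skr-3 (0.45, SE 0.22). The median log2 fold change was 4.36, and camera called the list up (adjusted p 1.19e-23, and adjusted p = 0.707 with an estimated correlation). pals-14 (WBGene00009061, chromosome I, 13139122 to 13141898) rose from 0.475 ± 0.138 to 35.2 ± 13.1 CPM (SD, n = 2), a log2 fold change of 6.19 (SE 0.41, edgeR adjusted p 0.00671). eol-1 (WBGene00045401, chromosome V, 13979462 to 13980907) rose from 0.623 ± 0.129 to 61.8 ± 34 CPM, a change of 6.62 (SE 0.52, edgeR adjusted p 0.00864). pals-37 and pals-33 rose by 6.14 (SE 0.54) and 4.36 (SE 0.38), and reads of pals-37 are shared with another gene. pals-5 had 3 counts in the control libraries together and 778 in the hsf-1 RNAi libraries, a ratio of 256 (95% counting interval 87.3 to 1245), and lost significance in edgeR without control replicate 1 (adjusted p 0.0553). eol-1, pals-14, pals-33 and pals-37 kept their calls with each library left out in turn. The number of called members was 8 without control replicate 1 and 8 without control replicate 2. Between the same groups, sperm and vitellogenin lists had medians of -0.62 and -1.61.

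Other large rises were in saposin-like and C-type lectin genes and in genes known only by sequence names. spp-9 (WBGene00004994, chromosome X, 11487784 to 11488203) rose from 0.312 ± 0.152 to 44.7 ± 14.5 CPM, a log2 fold change of 7.14 (SE 0.42, edgeR adjusted p 0.00671). clec-60 (WBGene00014046, chromosome II, 10480043 to 10481874) rose from 1.67 ± 0.877 to 193.1 ± 76.5 CPM, a change of 6.84 (SE 0.45, edgeR adjusted p 0.00671). spp-12 rose by 6.16 (SE 0.59). ZK355.8, T07H8.11, F42C5.3 and B0507.8 rose by 6.88, 6.88, 6.79 and 6.0. Y57E12B.11 had 0 counts in both control libraries and was at least 84.1-fold higher on hsf-1 RNAi. F42C5.3 and B0507.8 lost significance in edgeR without control replicate 1 (adjusted p 0.050 and 0.0539), and B0507.8 without control replicate 2 (adjusted p 0.050).

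Of 16 tested genes that depend on the p38 kinase PMK-1 and the factor ATF-7, 2 were lower, 1 was higher and 13 did not pass. The median was -0.90, and camera called the list down (adjusted p 4.8e-05, and adjusted p = 0.707 with an estimated correlation). The lower genes were clec-265 (WBGene00019738, chromosome X, 3031783 to 3033117), from 87.4 ± 17.8 to 22.2 ± 0.664 CPM (-1.97, SE 0.17, edgeR adjusted p 0.0103), and lys-2 (WBGene00003091, chromosome V, 10280307 to 10281474), from 897.7 ± 181.5 to 320.2 ± 38.6 CPM (-1.49, SE 0.19, edgeR adjusted p 0.0252). clec-60 was the 1 higher member. Adjusted over the list alone, 2 members were higher and 8 lower. Lower members numbered 4 without control replicate 2, without hsf-1 RNAi replicate 1 or without hsf-1 RNAi replicate 2. sysm-1 had a log2 fold change of -1.25 (SE 0.21), just outside the edgeR threshold (adjusted p 0.0503). The list of PMK-1 pathway components, with 14 genes, also holds genes of other kinase cascades, kgb-1 among them. Its median was 0.25 and camera called it up (adjusted p 0.00543). The call was lost without control replicate 1 (median 0.11) and with an estimated correlation (camera adjusted p = 0.707). The 1 member past the threshold was kgb-1, a JNK-like kinase gene, which rose by 1.21 (SE 0.19, edgeR adjusted p 0.0435). Adjusted over the list alone, 3 members were higher. The call of kgb-1 was lost in edgeR without control replicate 1 (adjusted p 0.0773) and control replicate 2 (adjusted p 0.105).

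Lysozyme and saposin-like genes changed in both directions. Of 37 tested, 4 were higher (spp-9, spp-12, spp-27 and lys-3) and 4 lower (lys-2, spp-18, spp-3 and ilys-5), against 8 and 11 adjusted over the list alone. spp-18 fell by 1.33 (SE 0.19), spp-3 by 1.15 (SE 0.17) and ilys-5 by 3.79 (SE 0.57) on the log2 scale, while lys-3 rose by 2.71 (SE 0.39) and spp-27 by 5.24 (SE 0.76). Only 1 member was lower without control replicate 1, where spp-18, spp-3, lys-3 and ilys-5 lost significance, as ilys-5 did without control replicate 2; 10 were lower without hsf-1 RNAi replicate 2. The list's mean was 0.29 and its median -0.26 (-0.089 without control replicate 1), and camera did not call it (adjusted p 0.37).

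C-type lectin genes also divided, with 8 of 101 tested members higher and 5 lower, and 12 and 16 adjusted over the list alone. The median was -0.38 (-0.055 without control replicate 1), and camera did not call the list (adjusted p 0.0858) except without hsf-1 RNAi replicate 2 (adjusted p 0.0136) among fits with a library left out. Beside clec-60, clec-86 rose by 3.35 (SE 0.23, edgeR adjusted p 0.00671) and clec-80 by 2.25 (SE 0.17, edgeR adjusted p 0.00864). clec-86 overlaps alh-10 on the other strand and clec-80 shares reads with another gene. The lower genes were clec-265, clec-186 (-1.78, SE 0.22), clec-52 (-2.25, SE 0.36) and the 2 gene copies named clec-209 (-3.20, SE 0.31), whose reads were divided equally between them. clec-186 lost significance without control replicate 1 and control replicate 2. The higher members numbered 5 without control replicate 1 or 2, and the lower members 8 without control replicate 2, 9 without hsf-1 RNAi replicate 1 and 12 without hsf-1 RNAi replicate 2. Of the genes tied to ZIP-2 and surveillance of core processes, 2 of 11 were lower. These were oac-32 (-3.04, SE 0.36, edgeR adjusted p 0.02) and irg-3 (-1.61, SE 0.26, edgeR adjusted p 0.0448). irg-3 passed with hsf-1 RNAi replicate 2 left out but not with any other library left out (adjusted p up to 0.161), and oac-32 did not pass without control replicate 2 (adjusted p 0.0617). Adjusted over the list alone, 2 were higher and 4 lower, and camera gave an adjusted p of 0.151 (0.0371 without hsf-1 RNAi replicate 2). The median was -0.12, between -0.48 and -0.22 with each library left out in turn and -0.0024 with library totals only. No ZIP-2-list member was lower without control replicate 2, 1 was without control replicate 1 and 3 were without hsf-1 RNAi replicate 2.

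Among genes of detoxification enzymes, 4 of 59 UDP-glucuronosyltransferases and 1 of 39 glutathione S-transferases were lower, and none of 53 cytochrome P450 genes passed in edgeR. Of the P450 genes, 1 higher and 9 lower had an unadjusted p under 0.05, DESeq2 called 4 and limma-voom 0, and in edgeR 2, 1 and 4 were lower without control replicate 2, hsf-1 RNAi replicate 1 and hsf-1 RNAi replicate 2. The lower UDP-glucuronosyltransferases were ugt-39 (-1.78, SE 0.19), ugt-48 (-1.73, SE 0.21), ugt-62 (-1.12, SE 0.14) and ugt-22 (-1.26, SE 0.21), with edgeR adjusted p from 0.0147 to 0.0472. Adjusted over the list alone 1 was higher and 12 lower. ugt-39 shares reads with another gene and ugt-48 overlaps cft-1 on the other strand. All 4 lost significance without control replicate 1, and ugt-62 also without control replicate 2; 6 members were lower without hsf-1 RNAi replicate 1 or 2. The glutathione S-transferase gene gst-24 (WBGene00001772, chromosome II, 13610443 to 13611366) fell from 309.6 ± 146.0 to 63.9 ± 11.4 CPM (-2.28, SE 0.33, edgeR adjusted p 0.035) and was the 1 lower member, against 2 adjusted over the list alone and 4 without hsf-1 RNAi replicate 2. Medians were -0.24 for UDP-glucuronosyltransferases, -0.38 for glutathione S-transferases and -0.23 for cytochrome P450 genes, with -0.14 for the first and -0.13 for the last without control replicate 1. Camera called these 3 lists down with the preset correlation, with adjusted p of 0.00412, 0.000416 and 0.00299. None passed with an estimated correlation (adjusted p = 0.707 for each), and the UDP-glucuronosyltransferases also failed without hsf-1 RNAi replicate 1 (adjusted p 0.091). Other falls were those of Y94H6A.10 (-3.28, SE 0.16), the arginine kinase gene argk-1 (-2.15, SE 0.35), T16G12.1 (-2.12, SE 0.28) and the carboxylesterase gene cest-1.2 (-1.97, SE 0.31). Of these 4, argk-1, T16G12.1 and cest-1.2 lost significance without control replicate 1 and without control replicate 2, and argk-1 without hsf-1 RNAi replicate 1.

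Of 23 intestine markers tested, 5 were higher and 1 lower, against 8 and 3 adjusted over the list alone. The list had a median of 0.13 (0.20 without control replicate 2) and was not called (camera adjusted p 0.0709), but was without control replicate 2 (adjusted p 0.0429) and hsf-1 RNAi replicate 1 (adjusted p 0.0275). ifb-2, an intestinal intermediate filament gene (WBGene00002054, chromosome II, 5750188 to 5754140), rose from 165.6 ± 14.9 to 756.8 ± 125.1 CPM (2.19, SE 0.17, edgeR adjusted p 0.00864), with some reads shared with another gene. ifo-1, which organises these filaments, rose by 1.99 (SE 0.16, edgeR adjusted p 0.00864), and eps-8, an actin regulator of microvilli, by 1.31 (SE 0.13, edgeR adjusted p 0.0112). ifc-2 (1.2, SE 0.15) and the cathepsin B-like gene cpr-4 (1.02, SE 0.15) were also higher. The aspartyl protease gene asp-1 (WBGene00000214, chromosome V, 19049562 to 19050752) fell from 1330 ± 14.6 to 522.3 ± 73.3 CPM (-1.35, SE 0.16, edgeR adjusted p 0.019). asp-1 lost significance in edgeR without hsf-1 RNAi replicate 1 (adjusted p 0.0682). Without control replicate 1 there were 3 higher members, since ifc-2 and cpr-4 lost significance, and ifc-2 also lost it without control replicate 2.

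**Figure D2:**
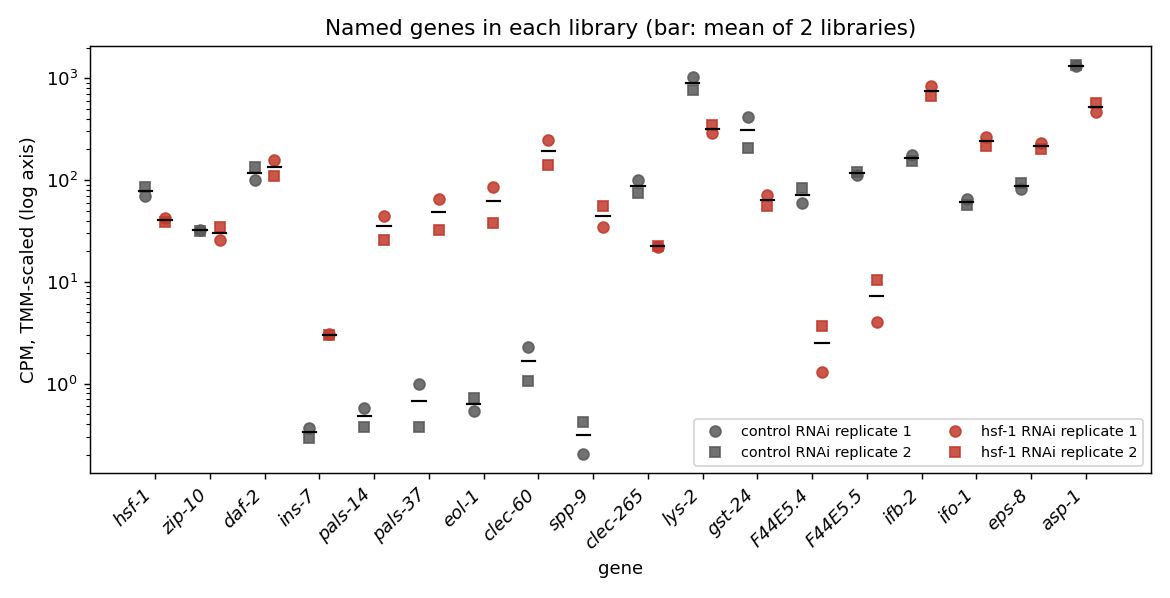
CPM in each library (vertical log axis) for 18 named genes, with control RNAi in grey, hsf-1 RNAi in red, replicate 1 as circles, replicate 2 as squares and group means as bars. hsf-1 is lower in both hsf-1 RNAi libraries, at 42.5 and 38.6 CPM, while zip-10 overlaps between the groups.

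zip-10 and daf-2 did not change detectably. zip-10 (WBGene00012101, chromosome V, 11650079 to 11650762) was at 32.1 ± 0.753 CPM on control RNAi and 30.2 ± 6.1 CPM on hsf-1 RNAi (SD, n = 2). Its log2 fold change was -0.09 (SE 0.19, 95% confidence interval -0.54 to 0.36, edgeR adjusted p 0.922), and it was 0.10 without hsf-1 RNAi replicate 1 and 0.022 with library totals only, a scaling that moves the median of all genes to 0.11. zip-10 overlaps exons of skp-1 on the other strand, and the counts cannot separate them. daf-2 (WBGene00000898, chromosome III, 2994514 to 3040846) had a change of 0.19 (SE 0.22, 95% confidence interval -0.34 to 0.71, edgeR adjusted p 0.851), which was -0.018 without control replicate 1 and -0.087 without hsf-1 RNAi replicate 1. Of 12 zip-family genes tested, none passed in edgeR, 4 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0. zip-1 had a change of 1.14 (SE 0.20, edgeR adjusted p 0.0623) and passed adjusted over the list alone with 1 other gene, zip-6. It passed over all genes tested without hsf-1 RNAi replicate 2 (adjusted p 0.0214), and it overlaps pph-4.1 on the other strand. The zip-family median was 0.13, between -0.024 and 0.31 with each library left out in turn, with a camera adjusted p of 0.26 (0.0384 without hsf-1 RNAi replicate 1).

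The insulin-like peptide gene ins-7 (WBGene00002090, chromosome IV, 9682011 to 9682845) rose from 0.331 ± 0.0525 to 3.03 ± 0.0276 CPM (3.17, SE 0.42, edgeR adjusted p 0.0271). Its call was lost in edgeR without control replicate 1 (adjusted p 0.0809) and control replicate 2 (adjusted p 0.0844). It was the 1 higher gene of 23 insulin-like peptides, over all genes tested and adjusted over the list alone, with a list median of 0.19 (0.44, -0.06 and 0.072 without control replicate 1, control replicate 2 and hsf-1 RNAi replicate 1) and a camera adjusted p of 0.0392, against adjusted p = 0.707 with an estimated correlation. It was also the 1 higher gene of 13 genes that are low in daf-2 mutants, where 2 were higher and 4 lower adjusted over the list alone, the median was -0.48 (-0.73 without hsf-1 RNAi replicate 1) and the camera adjusted p was 0.0583 (0.0422 and 0.016 without hsf-1 RNAi replicates 1 and 2). The 18 insulin signalling genes had a median of 0.17 (0.029, 0.26 and 0.075 without the same libraries in turn), with hsf-1 as the 1 lower member by either adjustment and a camera adjusted p of 0.0497. The signalling list had adjusted p = 0.707 with an estimated correlation. The camera call was also lost without control replicate 2 for the insulin-like peptides (adjusted p 0.37) and without control replicate 1 for the signalling genes (adjusted p 0.65), and for the latter also without hsf-1 RNAi replicate 1 (adjusted p 0.32). DAF-16 targets that are high in daf-2 mutants had a median of 0.20 (0.33 and 0.039 without hsf-1 RNAi replicates 1 and 2) and a camera adjusted p of 0.146 (0.0201 without hsf-1 RNAi replicate 1). Of these, dct-16 had a change of -0.73 (SE 0.20, edgeR adjusted p 0.209).

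None of 6 genes of vitellogenins, the yolk proteins, passed over all genes tested in edgeR, DESeq2 or limma-voom, while 6 had an unadjusted p under 0.05 and all 6 were lower adjusted over the list alone. Vitellogenin rows held 7.52% and 11.4% of counts in the control libraries and 2.78% and 5.59% in the hsf-1 RNAi libraries. vit-2 and vit-6 had changes of -1.0 (SE 0.40) and -1.12 (SE 0.42), with edgeR adjusted p of 0.487 and 0.422. Each passed in 1 of 11 alternatives, with changes over the alternatives from -1.54 to -0.61 and from -1.70 to -0.70. The median was -1.61 and camera called the list down (adjusted p 0.000299), though not without control replicate 2 (adjusted p 0.062) or with an estimated correlation (adjusted p = 0.707). Over all genes tested 4 vitellogenins were lower without hsf-1 RNAi replicate 2, where the median was -2.43. Sperm markers had a median of -0.62 over 57 genes and were called down (camera adjusted p 0.000231, and adjusted p = 0.707 with an estimated correlation), but the median was 0.15 without control replicate 1, -1.12 without control replicate 2 and -0.37 without hsf-1 RNAi replicate 2. Oocyte and eggshell markers had a median of 0.20 over 22 genes and were called up (camera adjusted p 0.00982, and adjusted p = 0.75 with an estimated correlation), with medians of 0.02 and 0.41 without control replicates 1 and 2. The oocyte call was lost without control replicate 1 (adjusted p 0.783) and hsf-1 RNAi replicate 2 (adjusted p 0.166), and the sperm call without control replicate 1 (adjusted p 0.666).

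None of 81 ribosomal protein genes passed in edgeR, DESeq2 or limma-voom, and 1 had an unadjusted p under 0.05. Their median was -0.22 (-0.14 without control replicate 1), and camera called the list down (adjusted p 1.99e-07, and adjusted p = 0.707 with an estimated correlation). Called up were also autophagy genes (median 0.20, camera adjusted p 0.0125), epidermal antimicrobial peptides (0.34, 0.0326) and hypodermis markers (0.23, 0.0451), and called down were body wall muscle markers (-0.14, 0.0297). Each of these 4 had adjusted p = 0.707 with an estimated correlation and lost its call with at least 1 library left out. These were control replicate 1 and hsf-1 RNAi replicate 2 for autophagy, any but hsf-1 RNAi replicate 2 for epidermal peptides, control replicate 2 and hsf-1 RNAi replicate 1 for hypodermis and each library for muscle. Without control replicates 1 and 2, medians were 0.050 and 0.35 for autophagy, 0.60 and 0.70 for epidermal peptides, 0.64 and 0.014 for hypodermis and -0.092 and -0.25 for muscle. Without hsf-1 RNAi replicate 1 they were 0.11 for hypodermis and -0.095 for muscle, and without hsf-1 RNAi replicate 2 the epidermal peptides were at 0.88. In all, camera called 18 of 37 lists with the preset correlation and none with an estimated correlation, a setting that also missed the shifted list in simulated data. The estimated correlations ran from -0.034 (hypodermis) to 0.99 (vitellogenins), with 0.61 for the intracellular pathogen response. Simulated genes were independent, so the simulation does not show that adjusted p from the preset hold for lists whose members move together. Beside the lists already named as not passing, camera did not call fatty acid metabolism (median -0.22), SKN-1 and antioxidant genes (-0.087), endoplasmic reticulum chaperones (0.11), mitochondrial chaperones (-0.013), the proteasome (-0.00012), histones (0.15), germline (0.029), zygotic embryo (0.16), pharynx (-0.053) and neuron markers (-0.071), and collagens (-0.079). Of these, camera called fatty acid metabolism without hsf-1 RNAi replicate 2 (adjusted p 0.00344), endoplasmic reticulum chaperones without control replicate 2 (adjusted p 0.0117) and histones without control replicate 1 (adjusted p 0.0165) or hsf-1 RNAi replicate 1 (adjusted p 0.0201). It called collagens and pharynx markers up without control replicate 1 (medians 0.72 and 0.41) and down without control replicate 2 (medians -0.47 for both). Adjusted over the list alone, 1 fatty acid metabolism gene was higher and 7 lower, and 1 epidermal peptide gene and 1 hypodermis marker were higher. Over all genes tested, 2 fatty acid metabolism genes were higher and 1 lower without hsf-1 RNAi replicate 1, and 1 higher and 6 lower without hsf-1 RNAi replicate 2. For mitochondrial chaperones, the proteasome, lysozymes and collagens the median, mean and test differed in sign. In the 23 lists without a member past the edgeR threshold, 70 of 699 distinct genes had an unadjusted p under 0.05. Of all 14639 genes tested, 1452 did, a similar share. DESeq2 called members of 6 of these lists and limma-voom of 0.

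**Figure D3:**
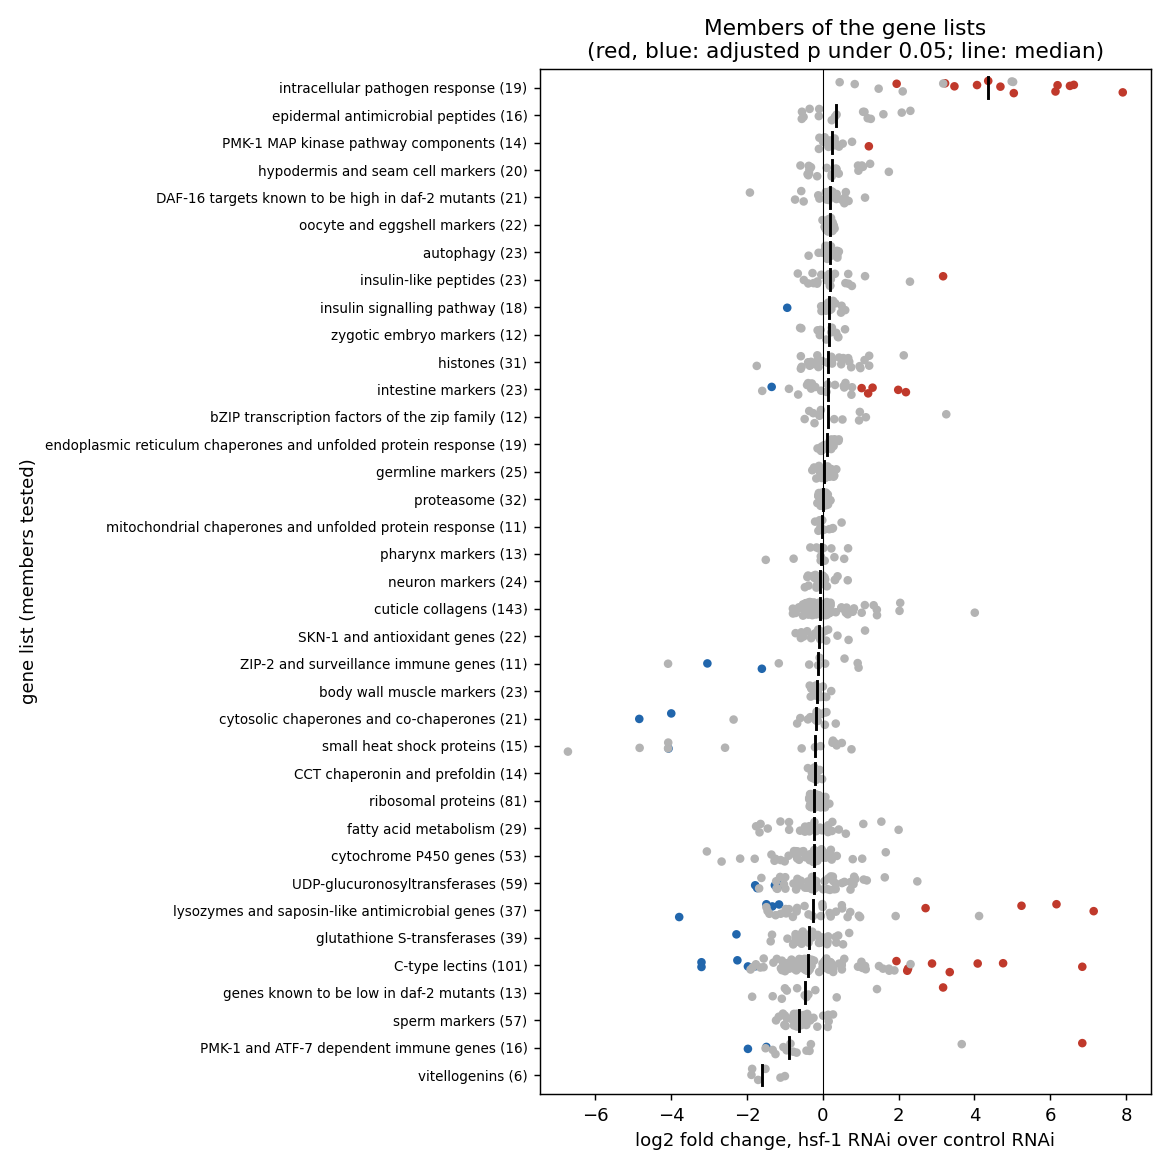
Log2 fold change on hsf-1 RNAi over control RNAi (horizontal axis) of each tested member of the 37 gene lists (vertical axis), with red and blue points past the edgeR threshold and a line at each median. The intracellular pathogen response lies farthest to the right, with a median of 4.36, and the vitellogenins farthest to the left, with -1.61.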

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

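The fit without vitellogenin rows was chosen after the data were seen, and the other alternatives before. Of 70 named genes, 67 kept their direction in every alternative, the exceptions being zip-10, daf-2 and hsp-1. Of 57 named genes past the threshold, 29 kept their call with each library left out in turn, and 26, 17, 3 and 1 lost it without control replicate 1, control replicate 2, hsf-1 RNAi replicate 1 and hsf-1 RNAi replicate 2. DESeq2 lost 0 of the 57, limma-voom 12 and library totals only 10. Alternatives planned for TPM or FPKM values were not run, since the files hold expected counts alone. Every main call with a value kept its direction in each alternative. With a library left out this is nearly fixed in advance, since the groups were separated in all 241.

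Counts of genes higher and genes lower by at least 2-fold are given as the total and the lower part. Without filter on low counts, genes changed by hsf-1 RNAi numbered 355, of which 110 were lower (95 at least 2-fold), with more genes tested. With library totals only, 34 were lower (30 at least 2-fold), and the median of all genes moved to 0.11. DESeq2 called 586 genes, 371 higher and 215 lower, and 444 at least 2-fold, 141 of them lower. At an adjusted p of 0.01, 19 genes passed (18 higher, 1 lower, all 19 at least 2-fold). At 0.1, genes changed by hsf-1 RNAi, higher, numbered 283 of 412, with 129 lower, and 360 changed at least 2-fold, with 106 lower. A test against a 1.5-fold change called 106, with 13 lower. With a library left out, the count ranged from 96 to 454 (77 to 273 higher, 19 to 181 lower), and at least 2-fold from 95 to 436, with 19 to 171 lower. hsf-1 ranged from -1.07 to -0.79. The replicate number as a block, with 1 residual degree of freedom, called 1100 genes (641 and 459) and 687 at least 2-fold, with 247 lower, including all 241. The deviations of same-numbered libraries had a correlation of 0.538 across genes, which are not independent replicates, and no label says that the numbers pair libraries.

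Camera with an estimated correlation and the directional fry test each called 0 lists, and the fry test of change in either direction kept 11 of the 18 called lists. zip-10 changed sign with library totals only (0.022). The direction of the list test reversed for some lists, given with their medians. Those were collagens (-0.046) and pharynx (-0.032) without filter, proteasome (-0.019), zip-family (-0.088) and histones (-0.052) with a filter of at least 5 CPM, collagens (0.016) and pharynx (0.028) with the replicate block, and the C-type lectins (median -0.38) in the directional fry test. With library totals only, the medians of collagens (0.024), pharynx (0.054), neuron (0.042), SKN-1 (0.028), mitochondrial (0.097) and proteasome lists (0.116) turned positive. So did collagens with limma-voom (0.025), while zygotic embryo markers turned negative with the 5 CPM filter (-0.143). The mitochondrial and proteasome medians, near 0, also crossed it in other settings. With a library left out, zip-10 ranged from -0.30 to 0.10, daf-2 from -0.087 to 0.43 and hsp-1 from -0.39 to 0.11. List medians ranged from 0.015 to 0.27 (endoplasmic reticulum), -0.091 to 0.13 (mitochondrial), -0.047 to 0.034 (proteasome), 0.039 to 0.33 (DAF-16 targets), -0.47 to 0.72 (collagens), -0.040 to 0.15 (germline), -1.12 to 0.15 (sperm), 0.020 to 0.41 (oocyte), -0.43 to 0.70 (zygotic embryo), -0.58 to 0.41 (pharynx) and -0.21 to 0.092 (neuron), where the test reversed. The medians of insulin-like peptides (-0.06 without control replicate 2) and the zip family (-0.024 without hsf-1 RNAi replicate 2) changed sign without that. Ranges were -0.35 to -0.12 for fatty acid metabolism, -0.14 to -0.013 for SKN-1 and 0.065 to 0.32 for histones, with the test in the same direction. Apart from fewer samples and the number of genes tested, the cause was not tested. At these depths, with 2 libraries per group, 42.8% of 2-fold changes were recovered in simulated data, among genes above a minimum mean count. The simulation did not vary depth alone.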

Other observations

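The tests of gene families, of neighbouring genes and of replicate number were chosen after the results were seen. So were the tests of age, paralogs and infection, of the share of intestine and of genes lower in deeper libraries; the test of expression level for the depth explanation and the test without vitellogenin rows were written before their results.

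Of 10 intermediate filament genes tested, 6 were higher, namely ifb-2 (2.19), ifp-1 (4.07, SE 0.34), ifd-2 (2.57, SE 0.30), ifc-1 (1.84, SE 0.18), ifd-1 (1.71, SE 0.22) and ifc-2 (1.2, SE 0.15). All 6 were higher in both hsf-1 RNAi libraries than in either control library, and ifd-1 and ifc-2 lost significance in edgeR without control replicate 1 or control replicate 2. A 1-sided Fisher's exact test with Benjamini-Hochberg adjustment over both directions was run on 371 families. All were formed by symbol prefix except the filaments, which were pooled by hand from several prefixes after their genes were seen to rise, so their adjusted p of 2.15e-07 does not cover that choice. The test gave 6.02e-18 for pals genes (15 of 33 higher), 0.00105 for math genes (5 of 21 higher) and 0.048 for fbxa genes (7 of 116 higher). P-glycoprotein genes were lower for 3 of 14 (adjusted p 0.00449), namely pgp-1 (-1.63, SE 0.15), pgp-8 (-1.84, SE 0.26) and pgp-9 (-1.12, SE 0.17). pgp-8 lost significance without control replicate 1, and pgp-9 without control replicate 1 or 2. C-type lectins passed in both directions (0.00449 and 0.00966), as UDP-glucuronosyltransferases did among the lower genes (0.0134). The 5 lower lectins include both copies of clec-209, whose equally divided reads enter the test as 2 genes. The test was not run with the copies merged, so the lower-direction result for lectins may rest on this. Genes of a family are not independent of each other.

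Higher genes often lay next to each other. Among tested genes in chromosome order, 25 neighbouring pairs were both higher, against a mean of 2.16 and a highest value of 9 in 10000 permutations of the calls (permutation p 1e-04, the smallest they can give). Y57E12B.11 and T07H8.11 are among the higher genes of chromosome V, at 6949517 and 6950807. Members of the families above also lie close together, such as the higher genes pals-39 and pals-38 on chromosome V, at 12441663 and 12445164. The permutations treated genes as independent and did not set families aside, so this result overlaps with that of the families.

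The rise of the intracellular pathogen response genes was weighed against 3 technical explanations. For age or stage, the larger median difference between libraries of a group was 0.87, against 4.36 between the RNAi groups. In replicate 2 minus replicate 1 the medians were -0.55 on control RNAi and -0.87 on hsf-1 RNAi. Of the 19 members, 13 were lower in replicate 2 in both groups. A larger difference in age or stage between the RNAi groups is not bounded by these values and cannot be told apart from the RNAi. Reads shared between paralogs are argued against, in part, by 18 members whose expected counts lay within 0.004 of whole numbers in all libraries. Their median was 4.22 and 11 of them passed. Whole counts do not prove that reads were unshared. They also arise where shared reads all go to a single copy, as for Y38C1AB.5 on hsf-1 RNAi. An infection of the hsf-1 RNAi cultures stays open, because both hsf-1 RNAi libraries (2 of 2) carried the rise and the tables hold no reads of a pathogen; it cannot be told apart from the RNAi.

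Libraries separated by replicate number within both RNAi groups, with 763 genes different between the numbers in the fit with a block (294 higher and 469 lower in number 2). Sperm, collagen and pharynx lists were lower in number 2 and oocyte, zygotic embryo and vitellogenin lists higher, in both groups, as a difference in age or stage could give (6 of 6 lists). Medians in number 2 minus number 1 were -1.2 and -0.46 for sperm and 0.66 and 1.23 for vitellogenins, on control and hsf-1 RNAi. The test of expression level came out on the side of depth, as only 41.7% of these genes lay above the median CPM of tested genes. A later test counted genes lower in number 2, the deeper library of both groups, by more than the larger log2 ratio of totals. These ratios were 0.078 on control and 0.20 on hsf-1 RNAi. It found 464 of the 763 genes, 184 of them above the median CPM, with median log2 differences of -1.46 and -0.90. Because 469 of the 763 were already called lower in number 2, this count largely restates that call. The collagen and sperm lists were fixed before the data were seen. In both groups 102 of 143 collagens and 45 of 57 sperm markers were lower in number 2, and 20 and 3 higher. Collagen medians were -1.05 on control and -0.60 on hsf-1 RNAi. Such falls in the deeper library exceed the difference in totals and argue against depth as their source. They do not cover genes outside these lists, and the test of expression level went the other way.

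Of the intestine markers, 5 were higher and 1 lower. A changed share of intestine as the source of the rises would move all markers alike. The median of all 23 tested markers was 0.13 with an SD of 0.956, against 1.31 for the 5 higher ones. Those 5 were selected for their rise in the same data, so this gap cannot decide on the share of intestine. Of the 23 markers, 13 had positive and 10 negative changes, from -1.60 to 2.19. Adjusted over the list alone, 8 were higher and 3 lower. These values over all markers argue against a changed share as the sole source, and a smaller part in the changes is not excluded. Vitellogenin counts taking up the libraries are argued against by the fit without those rows, where 5 stayed higher and 1 lower. A difference in age or stage between the groups cannot be told apart from the RNAi, since over all 23 markers the median absolute difference was up to 0.29 between libraries of a group and 0.598 between the RNAi groups, a gap smaller than the SD of 0.598 between markers; an infection was not tested for these genes.

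col-126 had counts of 0 and 84 in control replicates 1 and 2 and 0 and 92 in hsf-1 RNAi replicates 1 and 2. bath-25 had 0 and 64, and 2 and 123, in the same order, and abu-15 had 30 and 0, and 49 and 1.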
